A study of Homo sapiens with 4 samples.

How the data were processed

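Total RNA from 4 lines of KYSE 520 oesophageal squamous carcinoma cells was measured on Toray 3D-Gene human oligo chips, 1 array per line in 1 colour. Per the labels' protocols, cells were grown at 37°C under 10% CO2 in DMEM/F12 medium with 5% FBS, RNA was extracted with Trizol, and amplified amino-allyl RNA was coupled to the dye Cy5. The lines were grouped by their labelled FGFRL1 genotype, with the parent line and clone 1 as FGFRL1-intact and clones 15 and 21 as FGFRL1-deficient.

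Per the file headers, each scanner file holds the median intensity of 27456 spots at the wavelength of Cy5, joined by the scanner software from scans at 3 gains. Nothing had been subtracted from these intensities. A column of intensity around each spot correlated with the spot's own signal at r = 0.952 to 0.969 on the log scale over probes, so it was not used as a local background. The authors also deposited a table of processed intensity values on a linear scale. How these were made is not stated in the labels and was worked out by setting them against the scanner values of each array. The deposited intensity equals the spot's intensity minus the mean of the 2680 BLANK spots (highest and lowest 5% left out), scaled to a median of 25 per array. It is empty where the spot did not exceed that mean by 2 SD or carried a bad-spot mark. The largest residual of this rule was 5.9e-06, and it accounted for every empty cell.

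For the main values, background was corrected with limma's normal-exponential model fitted to the BLANK spots (function nec, robust, offset 16, the function's default), arrays were quantile normalized and log2 was taken. The offset was not written down before the data were examined, and it was set before any comparison was computed. The floor of each array was the trimmed blank mean plus 2 SD. Of 24460 probes, 30 were left out for a bad-spot mark on any array and 2121 for being above the floor on fewer than 2 of the 4 arrays, which left 22309. The percentage of probes above the floor was 89.8 in the parent line, 90.3 in clone 1, 90.5 in clone 15 and 89.8 in clone 21. Median probe intensity over the blank mean was 26.8, 23.6, 29.4 and 29.5 in the same order. Where a gene was under the floor on both arrays of a single genotype, or on the dimmer line of a comparison of single lines, the fold can be given as a lower bound. For each such array the bound uses the higher of the probe's own value and the lowest value above the floor.

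Gene names came from the scanner files. Of the probes, 17606 carried a current symbol, 2934 an older symbol updated through a synonym that belongs to a single gene in a table of the GRCh38.p14 assembly, 100 an ambiguous older symbol, 1944 another name and 1876 none. That table was used for names, chromosomes and gene order only. The updated names include ACKR3 (CXCR7 in the files), TCEAL9 (WBP5), SHOC1 (C9orf84) and NABP1 (OBFC2A). A gene was represented by its probe with the highest mean, which left 18286 genes.

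Genotypes were compared with limma's lmFit and eBayes (two-sided) on 2 lines against 2, with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. Prior degrees of freedom were 1.91 beside 2 residual ones. Genes at least 2-fold apart in the same direction in all 4 deficient-against-intact pairs were also counted. The 29 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in a single direction without comparing them with other genes, were alternatives. Comparisons between clone 1 and the parent line and between clones 21 and 15 rest on 1 array a side and are given as sizes and counts without p-values. The comparison of clones 15 and 21 with clone 1 is given as counts, and its limma fit is the alternative without the parent line. Medians of lists between 2 lines were ranked among 10000 random lists of the same size matched on mean level. Named genes were chosen by a fixed rule. For the genotype these were FGFRL1 and 12 genes in each direction, which for lack of genes past the threshold were those with the largest smallest-of-4-pairs difference. For each list these were up to 4 members with the largest absolute difference, and for each comparison of single lines 6 genes in each direction.

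The gene test and the 2-fold count were tried on simulated normalized log2 values of 4 lines. Noise was independent between genes, with spreads drawn from the fitted prior. Background correction, normalization and filtering were not simulated. Of 50 genes changed by 1 on the log2 scale, 42% passed the adjusted threshold, as did 68% of those changed by 2, 92% of those changed by 4 and 96% of those changed by 6. At least 2-fold in all 4 pairs were 16%, 94%, 100% and 100%. Of 18086 unchanged genes 4 passed the threshold and 44 were 2-fold apart in all 4 pairs. These rates did not carry over to the real data. There the 12 lower genes named for the genotype, at log2 differences of -3.98 to -6.27, had adjusted p of 0.0600 to 0.149 in limma.

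The design, the gene lists and most alternatives were set before the data were examined. Alternatives were median scaling, the deposited values with and without quantile normalization, subtraction of the blank mean without a model, offsets of 26 and 50, other filters, each line left out, other variance priors, other thresholds and other list tests. Of these the offset of 50 was chosen after seeing the data. The software was R 4.3.3 with limma 3.58.1, and plots were drawn with matplotlib 3.10.9.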

Results

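Messenger RNA levels were measured in 4 lines of KYSE 520, an established human oesophageal squamous cell carcinoma cell line, with a 1-colour oligonucleotide array and 1 array per line. FGFRL1 encodes a fibroblast growth factor (FGF) receptor family member that lacks the intracellular tyrosine kinase domain of the other receptors. The FGFRL1-intact group held the parent line (replicate 1) and clone 1 (replicate 2), which had gone through CRISPR-Cas9 treatment and kept an intact gene. The FGFRL1-deficient group held clone 15 (replicate 1) and clone 21 (replicate 2), for which both gene copies are labelled as disrupted. Each array carried 24460 gene probes, of which 89.8% to 90.5% were brighter than the background floor, and the median probe lay 23.6 to 29.5 intensity units above the blank spots. After filtering, 18286 genes were compared. Levels below are normalized log2 intensities with an offset of 16, so that folds of dim genes are understated. The 2 lines of a genotype served as its replicates. No label says that the lines were grown as repeated cultures. P-values of single genes therefore measure the spread between these lines, which includes technical spread, and the number of arrays limits the precision. Camera's p-values at the preset correlation set the genes of a list against the other genes, so they do not measure the spread between lines.

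FGFRL1 itself was lower in the deficient clones at the brighter of its 2 probes (H200014562). Its level was 8.08 ± 0.02 (SD, n = 2) in the intact lines and 6.97 ± 0.02 (SD, n = 2) in the deficient clones, a log2 difference of -1.10 (SE 0.07) or 2.15-fold. This gave a raw p of 0.000131 in limma and an adjusted p of 0.138, which misses the threshold. The second, dimmer probe (DHsGV10004826) differed by 0.005 on the log2 scale, with an adjusted p of 0.986. Where either probe lies relative to the disrupted part of the gene is not known here, so a level at a probe outside that part does not check the genotype labels.

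The comparison of the 2 genotypes addressed what differs in squamous carcinoma cells that lack FGFRL1. The genes with the largest differences were lower in the deficient clones. The level of ACKR3, an atypical chemokine receptor, was 10.71 ± 0.33 (SD, n = 2) in the intact lines and 4.44 ± 0.05 (SD, n = 2) in the deficient clones, 77.2-fold lower. GJB2, which encodes the gap junction protein connexin 26, was 75.7-fold lower and was above the floor in 1 of the 2 deficient clones. KRT14, the type I keratin of basal keratinocytes, stood at 13.88 ± 0.84 (SD, n = 2) against 8.52 ± 0.61 (SD, n = 2), 41.0-fold lower. SERPINB13, a serpin of squamous epithelium, was below the floor in both deficient clones and therefore at least 28.8-fold lower. MMP1, the interstitial collagenase, was 24.9-fold lower, and FGFBP1, a secreted carrier of FGFs, was 23.2-fold lower. A second, dim MMP1 probe differed by -0.10 on the log2 scale. The bone morphogenetic proteins BMP2 and BMP7 were 22.3-fold and 15.7-fold lower, with a second BMP7 probe at -1.78 on the log2 scale. IL20RB, a subunit of receptors for interleukin 20 family cytokines, was 22.1-fold lower, and TIMP3, an inhibitor of metalloproteinases held in the extracellular matrix, was 16-fold lower. The keratin genes KRT6A and KRT6C were 21.1-fold and 16.2-fold lower, but their near-identical transcripts can share a probe's signal, so the 2 values are uncertain as separate measurements. In the closest of the 4 deficient-against-intact pairs, these 12 genes were still 9.49-fold (KRT6C) to 64.1-fold (ACKR3) lower. Folds of genes that are dim in the deficient clones depended on the offset. With the deposited values as given and with an offset of 50, respectively, they were 307-fold and 30.7-fold for ACKR3, 280-fold and 9.30-fold for MMP1, 74.4-fold and 6.74-fold for TIMP3, 64.9-fold and 10.2-fold for BMP2, and 51.3-fold and 6.97-fold for BMP7. The deposited MMP1 values were 1.073 in clone 15 and 1.025 in clone 21, close to the floor, so its 280-fold is uncertain. GJB2 was 344-fold lower in clone 15 with the deposited values, which are empty in clone 21, and 27.2-fold lower with an offset of 50, and KRT6C was 10.6-fold lower with that offset. The bound for SERPINB13 was computed at the offset of 16 alone. Folds also moved by more than 1.5 times with an intact line left out, without the parent line and without clone 1 respectively, for MMP1 (51.2-fold and 12.1-fold), GJB2 (125-fold and 45.7-fold), BMP2 (36.2-fold and 13.7-fold), FGFBP1 (36.8-fold and 14.7-fold) and KRT14 (61.9-fold and 27.2-fold).

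**Figure D1:**
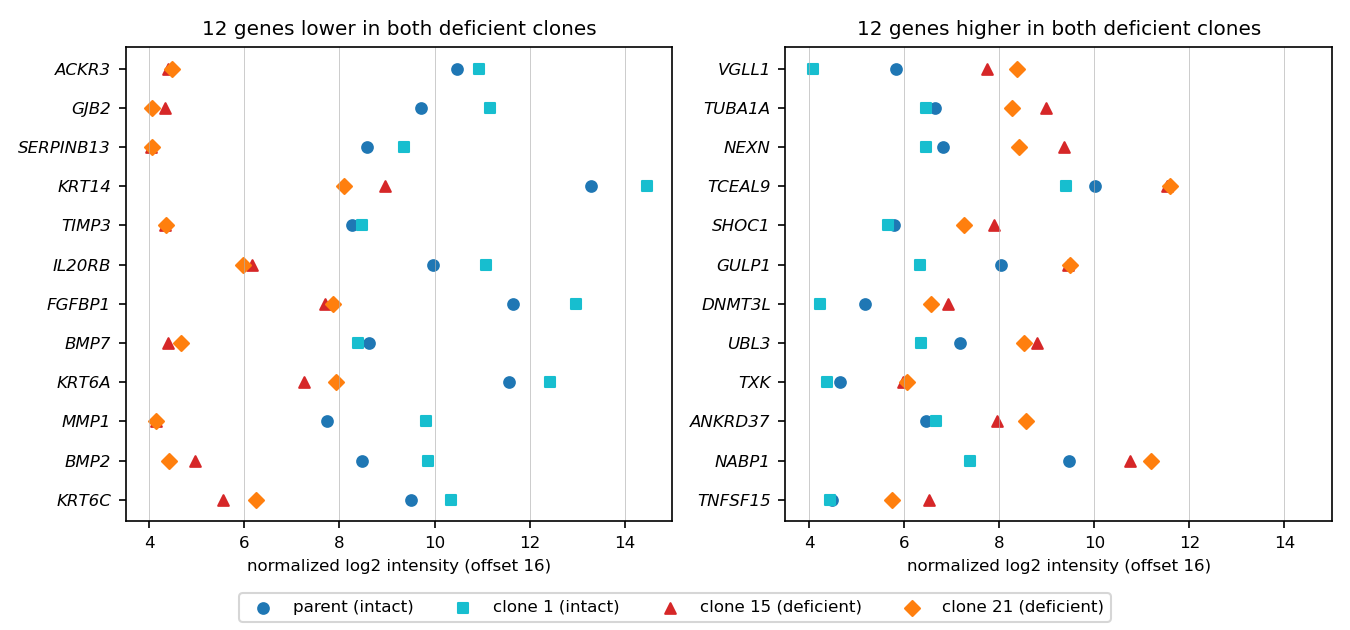
Normalized log2 intensity (offset 16, x axis) of the 12 genes with the largest lower and the 12 with the largest higher smallest-of-4-pairs difference, 1 symbol per line and array. In every gene both deficient clones lie on one side of both intact lines, with ACKR3 at 10.71 on average in the intact lines and 4.44 in the deficient clones.

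Genes that were higher in the deficient clones differed by less. VGLL1, a cofactor of TEAD transcription factors, stood at 4.96 ± 1.24 (SD, n = 2) in the intact lines, where it was above the floor only in the parent line, and at 8.05 ± 0.45 (SD, n = 2) in the deficient clones, 8.56-fold higher. NABP1, a single-stranded DNA-binding protein gene, was 5.81-fold higher, GULP1, an adaptor in the engulfment of apoptotic cells, 4.88-fold, and NEXN, an actin-binding protein gene, 4.71-fold. TUBA1A, an alpha-tubulin gene with close paralogs that can share its signal, was 4.21-fold higher, and DNMT3L, a cofactor of DNA methyltransferases, 4.09-fold. The remaining named genes were UBL3 (3.68-fold), SHOC1 (3.62-fold), TCEAL9 (3.59-fold), ANKRD37 (3.23-fold), the TNF superfamily ligand TNFSF15 (3.17-fold) and the kinase gene TXK (2.83-fold). A second TNFSF15 probe was 0.87 higher on the log2 scale. In the closest pair these 12 genes were 2.40-fold (TNFSF15) to 3.74-fold (VGLL1) higher. Without the parent line and without clone 1, respectively, the folds were 11.9 and 2.83 for NABP1, and 8.80 and 2.70 for GULP1. VGLL1, which is below the floor in clone 1, was 4.66-fold higher without clone 1. Without the parent line it was 15.7-fold higher, a value that rests on clone 1 as the only intact line. With the deposited values as given and with an offset of 50, respectively, the folds were 12 and 2.32 for DNMT3L, 8.81 and 1.87 for TNFSF15, and 7.35 and 1.73 for TXK. With that offset VGLL1 was 4.41-fold higher.

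Of the 18286 genes, 182 were at least 2-fold apart in the same direction in all 4 deficient-against-intact pairs, 50 of them higher and 132 lower in the deficient clones. At least 4-fold in all 4 pairs were 33 genes, all lower in the main values. That no higher gene reached 4-fold depended on the processing. In the deposited values TNFSF15 stood at 4.34 in the parent line, 3.98 in clone 1, 52.5 in clone 15 and 25.6 in clone 21. In the same order TXK stood at 6.3, 3.26, 32.5 and 34.1, so both were more than 4-fold higher in all 4 pairs. A 4-fold count with the deposited values is not given here. The authors' deposited values gave 138 higher and 202 lower genes at 2-fold in all 4 pairs. They carry no offset and also lack the normal-exponential model and quantile normalization, so the part of the offset alone is not known. Limma called 0 genes past an adjusted p of 0.05, and the smallest adjusted p was 0.0600. At an adjusted p under 0.1 there were 5 genes, all lower, namely TIMP3, ACKR3, KLK11, SERPINB3 and BMP7, of which KLK11 and SERPINB3 are named here after their values were seen. At an unadjusted p under 0.05 there were 3507 genes, 1784 higher and 1723 lower, where chance alone would give 914. The 2 genotypes did not overlap at 9591 genes (52.4%), where a random order of the 4 lines gives 33.3%. Any resemblance between the 2 lines of a group, whatever its source, raises this share, so it does not single out genotype. The other 2 ways of splitting the 4 lines into pairs gave 3 and 17 genes apart by 2-fold in all 4 pairs. Leaving out a line leaves 2 pairs to satisfy, and the count was then 770 without the parent line, 240 without clone 1, 364 without clone 15 and 382 without clone 21.

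**Figure D2:**
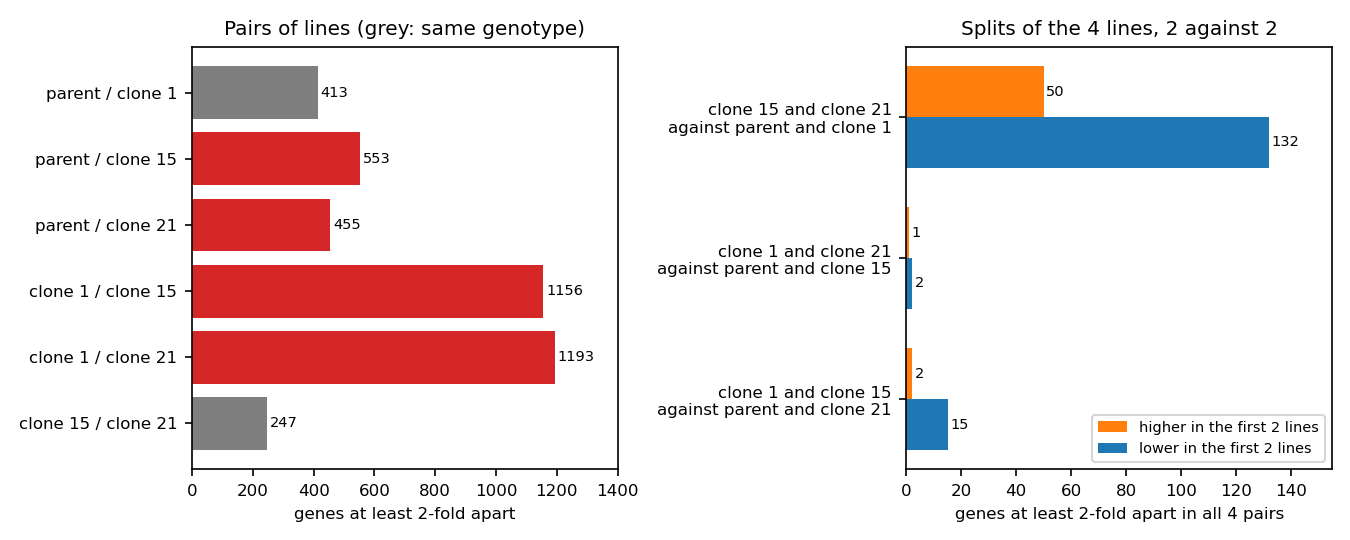
Left, number of genes at least 2-fold apart (x axis) for each of the 6 pairs of lines, with pairs of the same genotype in grey; right, number of genes at least 2-fold apart in all 4 pairs (x axis) for the 3 ways of splitting the 4 lines, higher in orange and lower in blue. The genotype split gave 50 higher and 132 lower genes, and clone 1 differed from clones 15 and 21 at 1156 and 1193 genes.

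Among 29 gene lists fixed before the data were examined, the list of basal keratinocyte genes had the largest difference. It was lower in the deficient clones, with a median log2 difference of -1.29 over 20 members (limma's camera, adjusted p = 6.65e-08). With an estimated correlation between genes the call was lost (adjusted p = 0.743), as it was with fry (adjusted p = 0.242). The estimated correlation rests on 2 residual degrees of freedom, and 0 of the 29 lists passed with it. A call lost there therefore cannot decide whether a list differs. Of its members 17 were lower in all 4 pairs and 1 was higher, and 7 were at least 2-fold lower in all 4. Adjusted over the list alone, 15 members were lower, against 0 over all probes tested. Its largest differences were those of KRT14 (-5.36) and KRT6A (-4.40), of PDPN (-3.27), which encodes podoplanin, and of TP63 (-2.18), which encodes the transcription factor p63 of basal squamous cells. In both intact lines these 4 genes lay above both deficient clones, and the list median was 0.53 higher in clone 1 than in the parent line. Genes of squamous differentiation were also lower, with a median of -0.28 over 31 members (camera, adjusted p = 9.35e-06). This call too was lost with an estimated correlation (adjusted p = 0.743), while fry kept it (adjusted p = 0.0407). In this list 20 members were lower and 0 higher in all 4 pairs, 4 were at least 2-fold lower in all 4, and 6 were lower when adjusted over the list alone. CSTA, which encodes the protease inhibitor cystatin A, differed by -2.90, the cornified envelope gene SPRR1B by -2.83 and the kallikrein KLK7 by -1.97. KLK5, another kallikrein, differed by 1.83, but its lines of the 2 genotypes overlapped.

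Hypoxia and glycolysis genes were lower in the deficient clones, with a median of -0.24 over 29 members and 14 members lower and 1 higher in all 4 pairs (camera, adjusted p = 0.0116). The adjusted p was 0.743 with an estimated correlation and 0.0845 without clone 1. The median difference of this list from the parent line was -0.23 in clone 15 (8 members higher), -0.15 in clone 21 (13 higher) and 0.37 in clone 1 (24 higher). Clone 1 thus lay further from the parent line than either deficient clone did. The median of the deficient clones was -0.17 against the parent line and -0.48 against clone 1. NDRG1 differed by -2.11, the glycolytic regulator PFKFB3 by -1.92, the aldolase gene ALDOC by -1.91 and DDIT4 by -1.77, and adjusted over the list alone 5 members were lower and 1, ANKRD37, was higher. NRF2 target genes had a median of -0.28 over 30 members, with 16 lower and 1 higher in all 4 pairs (camera, adjusted p = 0.0134). The adjusted p was 0.743 with an estimated correlation, 0.182 without the parent line and 0.0906 without clone 15. The median difference from the parent line was -0.55 in clone 15, -0.15 in clone 21 and -0.10 in clone 1, and clones 1 and 15 against the parent line and clone 21 gave -0.36 (adjusted p = 1.58e-05). The aldehyde dehydrogenase ALDH3A1 differed by -3.77 (SE 0.65). The aldo-keto reductases AKR1B10, AKR1C2 and AKR1C3 differed by -3.20, -2.78 and -1.84, the last pair being close paralogs. No member passed when adjusted over the list alone. Interferon-stimulated genes were higher on average, with a median of 0.32 over 36 members and 14 higher and 4 lower in all 4 pairs (camera, adjusted p = 0.0104). This did not hold for both deficient clones, since the median difference from the parent line was 0.32 in clone 21 (27 members higher), -0.06 in clone 15 (15 higher) and -0.29 in clone 1. Clones 1 and 15 against the parent line and clone 21 gave -0.40 for this list (adjusted p = 1.72e-08), a smaller p than the genotype split. The adjusted p was 0.743 with an estimated correlation, 0.232 without clone 1 and 0.382 without clone 21. The immunoproteasome subunit PSMB9 differed by 1.72, IFIT3 by 1.60, IFIT2 by 1.48 and BST2 by 1.45, and no member passed when adjusted over the list alone.

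**Figure D3:**
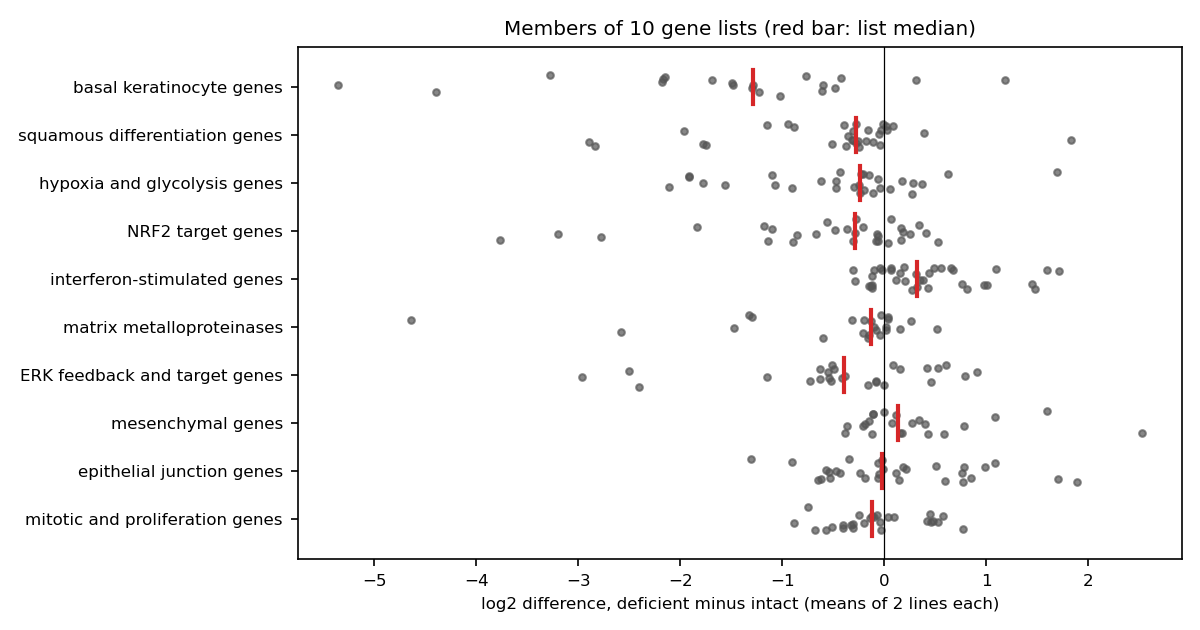
Log2 difference between the means of the 2 deficient and the 2 intact lines (x axis) for each member (grey points) of 10 of the 29 gene lists, with the list median as a red bar. The basal keratinocyte median lies at -1.29 and the squamous differentiation median at -0.28.

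Genes of FGF signalling did not move together. Over 28 FGF ligands, receptors and adaptors the median was 0.02 and the mean -0.26 (camera direction down, adjusted p = 0.819). FGFBP1 (-4.54) and the receptor FGFR3 (-2.50, SE 0.19) were the members at least 2-fold lower in all 4 pairs, and FGF13 differed by -1.26 and FGF12 by 0.84. Adjusted over the list alone, 2 members were lower and 1 higher. FGFR3 was also the largest difference among 29 genes near FGFRL1 at 4p16.3, whose median was -0.08 (adjusted p = 0.261). The next was SPON2 at -0.81. ERK feedback and target genes had a median of -0.40 over 26 members, with 13 lower and 7 higher in all 4 pairs, and did not pass (adjusted p = 0.149, passing at 0.0234 without the parent line, 0.0234 to 0.743 over all alternatives). The median difference of the ERK list from the parent line was -0.04 in clone 15, -0.18 in clone 21 and 0.29 in clone 1. Clones 1 and 15 against the parent line and clone 21 gave 0.24 (camera, adjusted p = 0.0108). The ERK phosphatase DUSP6 differed by -2.96, the EGF receptor ligand AREG by -2.51, the transcription factor EGR1 by -2.41 and EMP1 by -1.15. The level of DUSP6 was 7.78 in the parent line, 10.0 in clone 1, and 6.35 and 5.51 in clones 15 and 21. Matrix metalloproteinases had a median of -0.13 over 23 members (adjusted p = 0.0720), with MMP1 at -4.64, MMP10 at least 5.79-fold lower, MMP2 at -1.47 and MMP7 at -1.33. The list passed with the blank mean subtracted (0.0254) and without the parent line (0.0460), clone 1 (0.0276) or clone 21 (0.0109), and its adjusted p ranged from 0.0109 to 0.743 over all alternatives. No metalloproteinase passed when adjusted over the list alone. ETS transcription factors had a median of -0.08 over 26 members (adjusted p = 0.308), led by ERF (-1.01), ETS2 (-0.81), ELF3 (0.77) and ETV4 (-0.54), and 0 passed when adjusted over the list alone. The metalloproteinase and ETS lists were written with a recollection that a paper on these samples discusses some of their members, so they are not independent evidence of a direction. The plasminogen system and protease inhibitor list had a median of -0.19 over 15 members (adjusted p = 0.185), with TIMP3 at -4.03, SERPINB2 at -2.01, the protease ST14 at -0.99 and TIMP2 at 0.90. Notch pathway genes had a median of -0.12 over 24 members (adjusted p = 0.0859 with camera, 0.0276 without clone 1 and 0.0121 with fry, and 0.0121 to 0.743 over all alternatives). The ligands DLL1 and JAG1 differed by -2.01 and -1.26, and the target gene HES1 by -1.05, while HES5, below the floor in both deficient clones, was at least 1.52-fold lower.

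The other lists did not pass camera's test in the main setting. Mesenchymal genes had a median of 0.13 (adjusted p = 0.201), with fibronectin (FN1) at 2.52, TAGLN at 1.59, N-cadherin (CDH2) at 1.08 and COL5A1 at 0.78. Epithelial junction genes had a median of -0.02 and a mean of 0.11 (camera direction down, adjusted p = 0.826). Their largest differences were those of CLDN4 (1.88), RAB25 (1.71), DSG3 (-1.30) and CLDN7 (1.08). Integrin subunits had a median of -0.11 (adjusted p = 0.322), with ITGA6 at -1.50, its partner ITGB4 at -1.29, ITGA3 at -1.02 and ITGA4 at 0.87. Unfolded protein and amino acid stress genes had a median of -0.31 (adjusted p = 0.0714), with SLC3A2 at -1.14, SLC7A5 at -0.96, CTH at 0.93 and HSPA5 at -0.84. This list passed without the parent line (0.0234) or clone 15 (0.00104), within a range of 0.00104 to 0.743 over all alternatives. NF-kB and inflammatory genes had a median close to 0 (-0.0034, mean 0.01, camera direction down, adjusted p = 0.931) over members that went both ways, with interleukin 1 genes IL1B and IL1A at -3.38 and -1.76 and LCN2 and IL6 at 2.84 and 2.24. The level of LCN2 was 9.19 in the parent line, 5.57 in clone 1, and 10.07 and 10.38 in clones 15 and 21. The medians were 0.11 for p53 targets (adjusted p = 0.261), 0.10 for YAP targets (0.261), -0.17 for TGF-beta targets (0.304), and -0.04 for Wnt targets (0.814), whose mean was 0.04. They were 0.08 for DNA replication genes (0.261), -0.13 for mitotic genes (0.762), -0.19 for cholesterol synthesis genes (0.589), -0.11 for housekeeping genes (0.322) and 0.03 for ribosomal protein genes (0.533). DNA replication genes passed, upward, without clone 1 (2.17e-06) or clone 21 (0.00961) and turned downward without the parent line (0.0846) or clone 15 (0.687). Cholesterol synthesis genes passed, downward, without the parent line (0.0319) and turned upward without clone 1 (0.399) or clone 21 (0.746). The housekeeping list passed under median scaling (down, adjusted p = 0.0377), and the ribosomal list turned downward under it and with the deposited values as given. Among markers of other cell types, fibroblast genes had a median of -0.12 (adjusted p = 0.290), leukocyte genes of -0.0038 with a mean of 0.02 (adjusted p = 0.822) and endothelial genes of 0.03 (adjusted p = 0.931).

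The series names clone 1 as the control for clones 15 and 21. Against clone 1 both deficient clones were at least 2-fold apart at 771 genes, 432 higher and 339 lower. The genes furthest above clone 1 in both were MAGEA10, a cancer-testis antigen, 27.1-fold higher, LCN2, the iron-siderophore-binding lipocalin 2 (22.6-fold), ERP27, an endoplasmic reticulum protein gene (at least 18.9-fold, with clone 1 below the floor), the keratin KRT80 (14.1-fold), VGLL1 (at least 12.3-fold, with clone 1 below the floor) and CRIP1 (11.3-fold). For MAGEA10, LCN2, ERP27, KRT80 and CRIP1 the parent line lay nearer to both deficient clones than to clone 1. KRT80 stood at 11.38 in the parent line, 7.41 in clone 1, and 11.42 and 11.23 in clones 15 and 21. In the same order CRIP1 stood at 8.88, 5.47, 8.97 and 9.91. The genes furthest below were GJB2 (114.5-fold in clone 15, with clone 21 below the floor), ACKR3 (88.5-fold), MMP1 (51.1-fold), KRT14 (46.0-fold), SERPINB13 (at least 37.7-fold, with both clones below the floor) and FGFBP1 (34.6-fold). Of the 771 genes, 182 (23.6%) were also 2-fold apart from the parent line in the same direction in both clones, and 74 had no common direction in the 4 pairs. Against the parent line the corresponding count was 243, 74 higher and 169 lower. Unchanged lines set against a shared control gave 25.8 higher and 25.8 lower genes on average in 100 simulations, and independent lists of these sizes would share 23.8 higher and 14.4 lower genes against clone 1. The simulation already holds a shared control, with the spread fitted within genotypes, and the independent lists hold none. Part of the excess over the independent lists may therefore come from sharing a control. Part of the excess over both may come from a difference of clone 1 itself, which is 1 array. A limma fit of these 3 lines is given among the alternatives, as the setting without the parent line.

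Clone 1 and the parent line both carry the intact gene and differ by the CRISPR-Cas9 and cloning steps. They were at least 2-fold apart at 413 genes, 131 higher and 282 lower in clone 1. The inward-rectifier potassium channel gene KCNJ15 (7.26-fold), FEZ1 (6.74-fold), PTHLH, which encodes parathyroid hormone-related protein (5.53-fold), DUSP6 (4.65-fold), the cyclooxygenase PTGS1 (4.62-fold) and NEURL1 (4.49-fold) were higher in clone 1. NNMT, which encodes nicotinamide N-methyltransferase (23.0-fold), the calcium-binding protein gene S100P (21.8-fold), KRT80 (15.6-fold), MAGEA10 (13.2-fold), the vitamin D hydroxylase CYP24A1 (12.6-fold) and LCN2 (12.3-fold) were lower. By list, the medians for DNA replication (0.67), basal keratinocyte (0.53), cholesterol synthesis (0.53), hypoxia and glycolysis (0.37), mitotic (0.34) and ERK target genes (0.29) each lay above all 10000 random lists of matched size and level. Those of interferon-stimulated (-0.29) and epithelial junction genes (-0.23) lay below all 10000. These ranks describe 2 arrays and carry no replicate check.

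Clones 21 and 15, which share the deficient genotype, were at least 2-fold apart at 247 genes, 154 higher and 93 lower in clone 21. NNMT (25.9-fold), the kallikrein KLK6 (12.8-fold), complement C3 (9.32-fold), AKR1C2 (8.40-fold), WNT11 (8.13-fold) and AKR1B10 (6.97-fold) were higher in clone 21. The neurexin gene NRXN3 (22.2-fold), the activin-binding protein gene FST (11.2-fold), GPAT4 (10.6-fold), NFKB2 (10.2-fold), NEURL1 (8.62-fold) and the bradykinin receptor BDKRB1 (8.40-fold) were lower. By list, NRF2 targets (median 0.53) and interferon-stimulated genes (0.38) lay above all 10000 random lists, and DNA replication (-0.41) and cholesterol synthesis genes (-0.36) lay below all 10000. Again there was 1 array per line and no replicate check.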

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

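The offset of 50 was chosen after seeing the data; all other alternatives were planned. For the 24 genes named for the genotype, folds that moved by more than 1.5 times with the deposited values as given, with an offset of 50 or without a line are given in the report, except for SERPINB13, which is under the floor in both deficient clones. An offset of 26 also moved GJB2 (49.3-fold), MMP1 (16-fold) and SERPINB13, for which no fold is given because both deficient clones are under the floor. Subtracting the blank mean moved ACKR3 (297-fold), MMP1 (273-fold), TIMP3 (73.8-fold), BMP2 (62.5-fold), BMP7 (50.5-fold), DNMT3L (12.1-fold), TNFSF15 (8.82-fold) and TXK (7.44-fold). It also moved VGLL1, GJB2 and SERPINB13, for which no fold is given because a line under the floor lies close to 0 after subtraction. FGFRL1 was lower under every setting (log2 difference -1.22 to -0.93, adjusted p 0.0933 to 0.426). This FGFRL1 result is that of its brighter probe, which stood for the gene. The dimmer probe differed by 0.005 on the log2 scale in the main setting and was not followed through the other settings. The genotype test called 0 genes with limma in the main setting (3507 at an unadjusted p under 0.05), 2 lower genes (ACKR3 and TIMP3) with the deposited values, as given or quantile normalized, 3 lower with the blank mean subtracted, 6 lower with an intensity trend in eBayes and 5 lower at an adjusted p under 0.1. Median scaling, the offsets, the filters, robust eBayes and leaving out any line gave 0 (without the parent line, both deficient clones are fitted against clone 1). Genes 2-fold apart in all 4 pairs numbered 182 (50 higher, 132 lower). They numbered 340 (138 and 202) with the deposited values, 339 (143 higher) with these quantile normalized, 411 (170 and 241) with the blank mean subtracted and 101 (17 and 84) with an offset of 50. An offset of 26 left 28 higher. These offsets shrink folds of dim genes by construction. At 1.5-fold there were 657 (318 and 339) and at 3-fold 53 (3 and 50). Leaving out a line, which leaves fewer pairs to satisfy, gave 240 to 770, with 74 to 432 higher and 166 to 338 lower; the lowest were without clone 1 and the highest without the parent line. Counts for both deficient clones against clone 1, for clone 1 against the parent line and for clone 21 against clone 15 moved from 771, 413 and 247 to 1378, 967 and 727 with the deposited values, 1362, 961 and 732 with these quantile normalized, 1532, 1119 and 870 with the blank mean subtracted, 461, 214 and 131 with an offset of 50 and 2040, 1417 and 1037 at 1.5-fold. The median probe was 23.6 to 29.5 units above the blanks, and the part of low signal in these counts was not tested beyond these offsets and filters.

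Of the 29 lists 5 passed camera, 0 with an estimated correlation (adjusted p = 0.743 for each of the 5), 2 with fry and 5 to 8 with a line left out (8 without the parent line). Basal keratinocyte genes remained past the threshold with every line left out (adjusted p 2.14e-09 to 6.92e-07), and squamous differentiation genes likewise (8.12e-06 to 7.74e-05). The estimated correlation rests on 2 residual degrees of freedom, so the 0 calls with it cannot decide whether a list differs. With fry, basal keratinocyte genes (adjusted p = 0.242), interferon-stimulated genes (0.553), hypoxia genes (0.346) and NRF2 targets (0.540) were lost. With a line left out, adjusted p ranged from 1.51e-07 to 0.382 for interferon-stimulated genes, from 0.000149 to 0.0845 for hypoxia genes and from 3.35e-07 to 0.182 for NRF2 targets. The calls ended without clone 1 (0.232) or clone 21 (0.382) for interferon-stimulated genes, without clone 1 for hypoxia genes, and without the parent line (0.182) or clone 15 (0.0906) for NRF2 targets. Other lists gained a call in the direction of the main setting. These were metalloproteinases with the blank mean subtracted (0.0254) and without the parent line (0.0460), clone 1 (0.0276) or clone 21 (0.0109), stress genes of the unfolded protein list without the parent line (0.0234) or clone 15 (0.00104), ERK genes without the parent line (0.0234), and Notch genes without clone 1 (0.0276) and with fry (0.0121). They were also DNA replication genes without clone 1 (2.17e-06) or clone 21 (0.00961), cholesterol synthesis genes without the parent line (0.0319) and housekeeping genes under median scaling (0.0377). Some lists that did not pass in the main setting turned direction, and ribosomal genes then passed in 2 settings. Under median scaling NF-kB genes turned upward (adjusted p = 0.973) and ribosomal genes downward (2.93e-06). With the deposited values epithelial junction genes turned upward (0.96) and ribosomal genes downward (0.000852). NF-kB genes turned upward with the blank mean subtracted (0.944). Endothelial markers turned downward with an offset of 50 (0.949), without a filter (0.992) and with fry (0.988), and leukocyte markers with the filter on all 4 arrays (0.992). Leaving out a line turned lists without any of them passing in the turned direction. These were epithelial junction (0.299), DNA replication (0.0846) and NF-kB genes (0.974) without the parent line, and mitotic (0.399), cholesterol (0.399), Wnt (0.890), endothelial (0.751) and ribosomal genes (0.751) without clone 1. They were ETS (0.998), DNA replication (0.687) and endothelial genes (0.977) without clone 15, and NF-kB (0.595), cholesterol (0.746), leukocyte (0.946) and ribosomal genes (0.806) without clone 21. Over all 4 fits without a line, turned or not, adjusted p ranged from 0.299 to 0.977 for epithelial junction, 2.17e-06 to 0.687 for DNA replication, 0.463 to 0.974 for NF-kB, 0.0818 to 0.9 for mitotic, 0.0319 to 0.746 for cholesterol, 0.687 to 0.9 for Wnt, 0.701 to 0.977 for endothelial, 0.159 to 0.806 for ribosomal, 0.151 to 0.998 for ETS and 0.499 to 0.946 for leukocyte genes. The cause was not tested in these cases. Fits without a line assume that the lone line of a genotype varies like the other genotype's lines. Deposited values and the filter on all 4 arrays give no value for genes that are empty or dim in a genotype, such as SERPINB13. No paired analysis was possible because the clone numbers name clones and do not tie lines across genotypes.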

Other observations

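Genes of DNA replication were higher in clones 1 and 15 than in the parent line, and less so in clone 21. Of 33 members, 32 were higher in clone 1 than in the parent line, 32 in clone 15 and 23 in clone 21. The median log2 difference from the parent line was 0.67 in clone 1, 0.62 in clone 15 and 0.23 in clone 21, and clone 21 differed from clone 15 by -0.41. The comparisons with the parent line share its single array, so they are not independent of each other. Among 10000 random lists of matched size and level, 0 reached the first 2 medians and 17 the third. The members that differed most by genotype were CCNE2, which encodes cyclin E2, with 5.57 in the parent line and 6.62, 7.53 and 6.67 in clones 1, 15 and 21, and POLE2 with 7.29 in the parent line and 7.03, 8.33 and 7.92 in the clones. Neither gene shows the order of the list medians. In both, clone 21 lay above clone 1, and POLE2 was lower in clone 1 than in the parent line. Cholesterol synthesis genes followed a similar order, with median differences from the parent line of 0.53, 0.19 and -0.15 in clones 1, 15 and 21. Interferon-stimulated genes ran the other way, with medians of -0.29, -0.06 and 0.32, and 27 of 36 members were higher in clone 21 than in the parent line. NRF2 targets were lowest in clone 15 (median -0.55 from the parent line, with 2 of 30 members higher) and less low in clone 21 (-0.15) and clone 1 (-0.10). Each value rests on 1 array per line.

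Several tests below were chosen only after the result was seen, namely those of clone 1 as the source of the list differences, those over other splits of the lines, and those of the share of chromosome 15 genes and of random gene sets. The tests of paralogs, of dim probes, of normalization and of the chromosome's parts were set before their results were seen. The first pattern is the lower level of keratinocyte lists in the deficient clones. If a shift of clone 1 alone had made it, the deficient clones would sit near the parent line, but the basal list's median was -1.0 against the parent line (bootstrap 95% interval over members -1.49 to -0.65, 18 of 20 members lower in both clones), and that of the squamous list was -0.23 (-0.33 to -0.11, 22 of 31 members). The values also argue against signal shared among keratin, laminin and integrin paralogs for the basal list, since the 9 members outside these families had a median of -0.77 (-2.18 to -0.43). For the squamous list the 14 members outside its paralog families had a median of -0.23 with an interval of -0.36 to -0.01, which leaves shared signal open. These bootstrap intervals resample genes measured on the same arrays, which are not independent replicates, so they do not measure the spread between lines. Each genotype was represented by 2 lines, so an effect of losing FGFRL1 and a difference between clones unrelated to it both remain open and untested.

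The 4 lines can be split 2 against 2 in 3 ways, so a share under 0.05 cannot be reached. As many genes 2-fold apart in all 4 pairs as the real 182 came from 1 of the 3 splits, the real one, and the highest other count was 17. As many lists past camera as the real 5 came from 2 of the 3 splits, with 9 lists for clones 1 and 15 against the parent line and clone 21. Those lists include DNA replication (adjusted p = 1.7e-24), cholesterol synthesis (4.01e-10), interferon-stimulated genes (1.72e-08) and NRF2 targets (1.58e-05). With an estimated correlation each split gave 0 lists, so that setting does not separate the splits.

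The second pattern is that the deficient clones lay further from clone 1 than from the parent line. Clone 1 was 2-fold from clones 15 and 21 at 1156 and 1193 genes and the parent line at 553 and 455, while clone 1 and the parent line were 2-fold apart at 413. Scatter of dim probes would shrink this among bright genes, but among 4003 genes with a mean log2 level of at least 8 the deficient clones differed 2.44 times as often from clone 1 as from the parent line (792 against 325). Normalization would end it under other processing, but the ratio, 2.33 in the main values, stayed at 1.74 or above in the other 4 processings. Each of these scales or quantile normalizes whole arrays, so they do not test for other distortions of clone 1's single array. A difference that clone 1 acquired during treatment and cloning, or in culture, may be a source of this greater distance and was not tested.

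The third pattern is that, of 248 chromosome 15 genes with a mean log2 level of at least 6, 91.1% (exact 95% interval 86.9 to 94.4) were lower in clone 21 than the mean of the other 3 lines (after the median over all autosomal genes was set to 0), so a few strongly changed genes do not account for it. The exact interval treats genes of the same arrays as independent and does not measure the spread between arrays. The median was -0.50 on the log2 scale, or 0.705 of the level in the other lines, whereas 10000 random sets of the same size and level lay between -0.08 and 0.09. A lost or thinned copy of the chromosome in clone 21 is a candidate explanation that stays open, since the medians of the 124 genes in the first part and the 124 in the second part of its gene order (-0.39 and -0.58) decide nothing: any 124 of these genes would have a median of -0.20 or lower. Against the parent line alone the median was -0.41 in clone 21, -0.00033 in clone 15 and 0.20 in clone 1, and DNA copy number was not measured; of the 88 combinations of 22 autosomes and 4 lines, 81 had medians within 0.2 of 0, and the next largest were those of chromosome 18 in clone 1 (-0.31) and chromosome 15 in clone 1 (0.31).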
